A study of Danio rerio with 9 samples.

How the data were processed

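Total RNA of single zebrafish embryos (Danio rerio) at about 25 hours post fertilization, raised at 29 °C, was made into libraries with the Illumina TruSeq RNA kit (version 2), per the labels' protocols. Groups were taken from the labels' phenotype: 4 normal and 5 coloboma embryos, each a separate embryo, so that the replicates are biological. Genotypes of single embryos were not stated in the sources used here, beyond an unexplained tag WT in the column names of the normal embryos. Library and sequencing dates were not given either, so no batch was tested.

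The deposited estimated counts (one value per gene symbol and embryo) were taken to be expected counts that the authors had rounded, since RSEM is among the tools in the submitters' processing notes. Those notes name CASAVA 1.8.2, RSEM 1.2.18, Bowtie 1.1.1 and the genome build Zv9. The annotation and the part each tool played were not given in the sources used here. The values are whole numbers, and the smallest total of a gene over the 9 embryos is 10. The deposited TPM values (length-scaled transcript abundances) by the authors cover the same genes. They keep no depth and served as an alternative only. The column names matched the sample labels, and no value column was left unmapped.

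Counts were rounded, which changed nothing, and tested with edgeR 4.0.16 in R 4.3.3: low genes were removed by filterByExpr (minimum count 10), TMM factors were applied, and a quasi-likelihood F test compared coloboma with normal embryos with no covariate. Of 22337 genes, 21293 were tested. P values were adjusted by Benjamini-Hochberg and the threshold was 0.05. Log2 fold changes are coloboma minus normal, with the SE taken from the fold change and the F value. Levels are TMM-scaled CPM, given as mean ± SD. Single levels and shares were compared by two-sided exact permutation over the 126 splits of 9 embryos into 4 and 5. Intervals have a confidence level of 95% and, like the floor of 3 counts used for a group at 0, cover counting error only. The common biological coefficient of variation was 0.199.

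The test, the named genes, the gene lists and the alternative settings were chosen before the data were examined. Named genes were zic2a, zic2b and alx1 whatever their values, the 10 genes with the smallest p in each direction among those past the threshold that had a proper symbol, and up to 4 members with the smallest p of each list described. Genes named outside this rule are said to be so, and some results on single genes are not reported here. The lists, 38 in number, covered the zic family, neural crest, pigment cells, eye and forebrain, signalling pathways, and the other tissues and states of a whole embryo, and were tested with camera (limma 3.58.1, voom values, preset correlation 0.01), with Benjamini-Hochberg over the lists. Camera with an estimated correlation and fry were run beside it. Of 841 list entries, 725 matched by symbol, 21 by an alias in the list and 30 by a synonym in the reference table, 6 fell on a gene already in the list and 59 were not matched. A list level is the mean log2 CPM of its members in an embryo minus the mean of the normal embryos.

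The steps were tested on simulated data drawn from the means and library sizes of the real embryos for this comparison, over 21293 genes with 200 changed. Of 50 genes each, 26.0% were recovered at a log2 change of 0.5, 82.0% at 1, 100% at 2 and 98.0% at 3, and 7 of 160 calls (4.38%) were false. Of 100 simulated unchanged lists of 25 genes, 2 had a p below the threshold and 0 passed after adjustment, while a list raised by 0.5 had a camera p of 2.67e-35. The simulated genes were drawn independently of each other, whereas the correlations estimated in the real lists ran from 0.03 (pronephros) to 0.78 (erythroid). The simulation therefore does not show how often the preset test calls unchanged lists of correlated genes.

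Replicates were compared before averaging: within each group all pairs of embryos differed beyond sampling noise, with chi-square per degree of freedom from 26.8 to 78.5. Normal embryos 3 and 4 (31.9) and 6 and 7 (40.5) were closer than the other normal pairs (70.0 to 78.5). Among coloboma embryos, 6 and 7 (26.8) and 4 and 5 (33.0) were the closest, and embryo 3 was nearest to 6 (42.1). The labels name no batch or clutch, and whether these pairs share one was not tested. The authors' build was not used for positions. The chromosomes of genes and their order came from a RefSeq gene table of assembly GRCz12tu, matched by symbol, and no coordinates were taken from it. Genes with near-identical copies, such as the crystallins and the fast myosin heavy chains, share reads, which an estimator such as RSEM divides by a model, so their single values are uncertain. The kit does not mark strand, so that overlapping genes on opposite strands cannot be told apart.

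Alternatives covered other scalings, tests (DESeq2 1.42.0, voom with and without sample weights, robust edgeR), filters, TPM input, thresholds, 1 surrogate variable (sva 3.50.0), a replicate block and leaving out each embryo. Leaving out coloboma embryos 3 and 5 together, and leaving out the genes of the zic2a chromosome, were added after the data were seen.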

Results

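RNA sequencing was carried out on 9 single zebrafish embryos at about 25 hours post fertilization. All came from matings of fish that carried one disrupted copy of zic2a and one of zic2b. These genes encode zinc-finger transcription factors of early brain and eye development. The embryos had been sorted by eye phenotype into 4 normal embryos (numbers 3, 4, 6 and 7) and 5 embryos with coloboma (numbers 3, 4, 5, 6 and 7). Coloboma is a gap left in the eye where the choroid fissure stays open. Each embryo was one library and one replicate. The labels stated no genotype for any embryo. The columns of the normal embryos bore the tag WT and those of the coloboma embryos the tag COL. Whether WT stands for a genotype or for a normal eye was not said. The deposited table held counts for 22337 genes, with total counts of 46255700 ± 5929400 (SD, n = 4) in the normal and 44031000 ± 16998000 (SD, n = 5) in the coloboma embryos. The lowest total was 20461180 in coloboma embryo 5 and the highest 59233104 in coloboma embryo 6. Mitochondrially encoded genes took 2.98% ± 0.371 (SD, n = 4) and 2.87% ± 0.291 (SD, n = 5) of the counts. The 20 most abundant genes of each library took 11.9% ± 0.826 (SD, n = 4) in normal and 13.7% ± 0.869 (SD, n = 5) in coloboma embryos.

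The comparison asked which genes differ between siblings with and without coloboma. The study's stated subject is the part of zic2 in the neural crest around the eye and in the shaping of the choroid fissure. Of 21293 genes tested, 44 passed an adjusted p of 0.05 (edgeR quasi-likelihood test, Benjamini-Hochberg), 17 higher and 27 lower in the coloboma embryos. Among the genes that fell were 8 of yellow pigment cells or of pteridine synthesis, lower by about 1.57 to 2.09 times, a grouping made after the values were seen. Skeletal muscle genes as a list were higher, and lists of pigment, crest, forebrain and retinal genes were lower, by camera with its preset correlation. Of the 38 lists, 20 passed that test (7 higher, 13 lower), and 0 passed with an estimated correlation, where 4 had an unadjusted p under 0.05. With the embryo as the unit, no list level passed a two-sided exact permutation test adjusted over the 38 lists (smallest adjusted p = 0.151). The 126 possible splits allow no p below 0.00794 in that test, and lists at this floor had the adjusted p of 0.151. The adjusted test could therefore not pass a list standing alone, and its outcome says little against the lists. Of the 37 genes past the threshold that could be placed, 19 lay on the chromosome that carries zic2a. Scaling by library size alone gave 12 higher and 33 lower genes, against 17 and 27 with the main scaling. In other settings the balance turned, as with DESeq2 (367 higher, 211 lower) or without coloboma embryo 5 (165 higher, 70 lower).

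The targeted genes themselves did not pass the test. Normalised zic2a counts were 47.8 ± 4.86 CPM (counts scaled to library size; SD, n = 4) in normal and 51.7 ± 6.62 (SD, n = 5) in coloboma embryos, a log2 fold change of 0.11 ± 0.11 (SE; edgeR adjusted p = 0.733; two-sided exact permutation p = 0.365). For zic2b the levels were 48.7 ± 4.15 CPM (SD, n = 4) and 47.7 ± 1.21 CPM (SD, n = 5), a log2 fold change of -0.03 ± 0.08 (SE; edgeR adjusted p = 0.908; two-sided exact permutation p = 0.754). A count over a whole gene does not separate intact from disrupted transcripts. With no genotypes stated in the labels, these levels checked no label. The smallest p that the 126 splits of the embryos allow is 0.00794.

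Those 8 genes are linked to xanthophores, the yellow pigment cells that derive from the neural crest, or to their pteridine pigment. GTP cyclohydrolase gch2, the first enzyme of pteridine synthesis, fell from 255 ± 31 CPM (SD, n = 4) to 139 ± 8.28 CPM (SD, n = 5), a log2 change of -0.88 ± 0.09 (SE; edgeR adjusted p = 0.00358). Xanthine dehydrogenase xdh fell from 9.95 ± 1.25 CPM (SD, n = 4) to 4.96 ± 0.730 CPM (SD, n = 5; edgeR adjusted p = 0.0120). The aldehyde oxidase aox3 changed by -0.87 ± 0.12 on the log2 scale (SE; edgeR adjusted p = 0.0120). The sugar transporter family members slc2a11b and slc2a15a changed by -0.90 ± 0.10 and -0.85 ± 0.10 (edgeR adjusted p = 0.00378 and 0.00390). The pteridine enzyme genes PTS, for pyruvoyl-tetrahydropterin synthase (-0.73 ± 0.11, edgeR adjusted p = 0.0274), and sprb, for sepiapterin reductase (-1.06 ± 0.17, edgeR adjusted p = 0.0403), fell too. So did the transporter gene slc2a15b (-0.65 ± 0.11, edgeR adjusted p = 0.04997). These 3 genes were chosen after their values were seen. Their calls were lost in 10 of 29 alternative settings for PTS, 9 of 29 for sprb and 16 of 29 for slc2a15b. For each of these 8 genes the change exceeded the SD of either group, which largely follows from their having passed the test and adds no support. None of the 7 that could be placed lay on the chromosome that carries zic2a. The xanthophore receptor gene csf1ra (-0.41 ± 0.14, log2, SE; chosen after its value was seen) did not pass over all genes (edgeR adjusted p = 0.294).

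In the list of pigment cell genes fixed beforehand, 3 of 23 members passed over all genes (gch2, xdh and aox3), all lower, and 11 were lower when adjusted over the list alone. Positive values were found for 4 members. The median log2 change of the list was -0.37 (camera adjusted p = 5.29e-09; adjusted p = 0.376 with an estimated correlation). The next member by p, gpr143, a melanosome receptor gene on the chromosome of zic2a, measured 5.33 ± 0.800 CPM (SD, n = 4) and 3.31 ± 0.432 CPM (SD, n = 5), with an edgeR adjusted p of 0.113. The melanin synthesis genes tyrp1a (-1.04 ± 0.26, log2, SE), tyrp1b (-0.49 ± 0.15), dct (-0.45 ± 0.16, on the chromosome of zic2a) and tyr (-0.37 ± 0.17), chosen after their values were seen, did not pass over all genes, and all but tyr were lower when adjusted over the list alone.

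**Figure D1:**
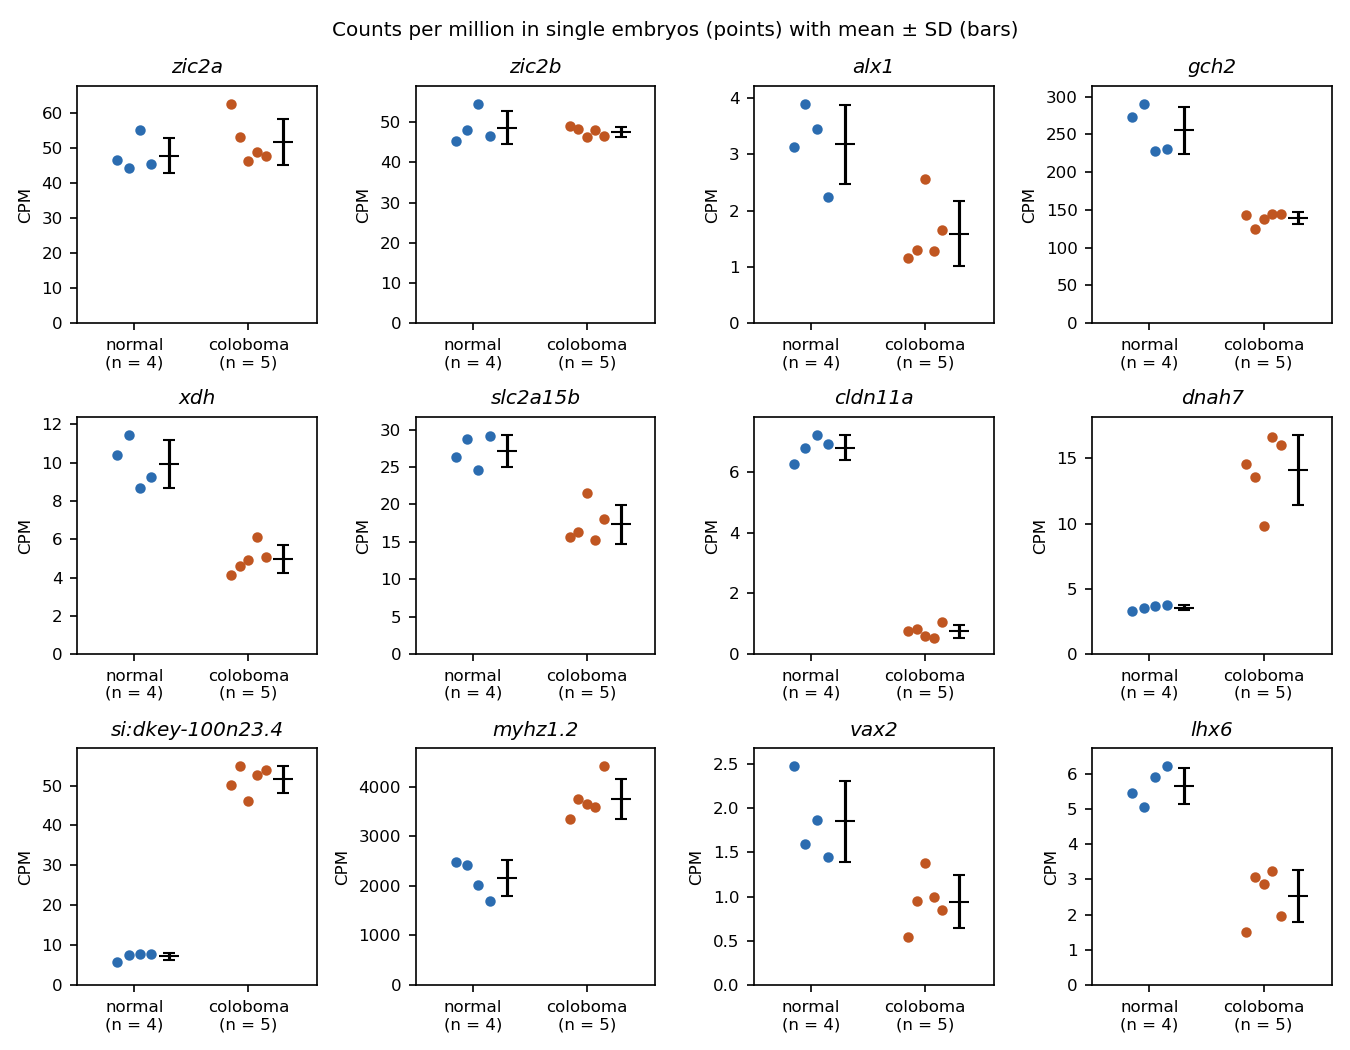
Normalised counts (CPM, y axis, linear, from 0) of 12 genes in the 4 normal and 5 coloboma embryos; each point is one embryo and the bars give mean ± SD. The groups do not overlap for gch2, xdh, slc2a15b, cldn11a, dnah7, si:dkey-100n23.4, myhz1.2, vax2 or lhx6, while zic2a, zic2b and alx1 overlap; vax2, lhx6, alx1, zic2a and zic2b did not pass the test.

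No member of the crest and eye lists other than the pigment cell list passed over all genes. The periocular crest transcription factor alx1 measured 3.18 ± 0.700 CPM (SD, n = 4) in normal and 1.59 ± 0.575 CPM (SD, n = 5) in coloboma embryos, a log2 fold change of -1.03 ± 0.25 (SE; edgeR adjusted p = 0.150; two-sided exact permutation p = 0.0238), and passed in 3 of 28 alternative settings. None of the 11 measured members of the periocular crest list passed over all genes, and 2, alx1 and alx4a, were lower when adjusted over the list alone. The related alx4a was at -0.50 ± 0.13, tfap2b at -0.55 ± 0.20 and foxc1b at -0.32 ± 0.13 (log2, SE). The list had a median log2 change of -0.19 (camera adjusted p = 0.000236; adjusted p = 0.376 with an estimated correlation).

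The pharyngeal skeletogenic crest list, genes of the crest that builds the face, had a median log2 change of -0.27 over 20 members (camera adjusted p = 4.96e-07; adjusted p = 0.376 with an estimated correlation). No member passed over all genes and 8 were lower when adjusted over the list alone, led by dlx4a (-0.69 ± 0.15, log2, SE), prrx1b (-0.35 ± 0.08), dlx2a (-0.69 ± 0.16, a gene on the chromosome of zic2a) and barx1 (-0.60 ± 0.14). In the early and migrating crest list none of 15 members passed over all genes or adjusted over the list alone, and the list itself did not pass (median -0.01; camera adjusted p = 0.165), although it did as lower without coloboma embryo 3 (camera adjusted p = 0.0227). Its members with the smallest p were pax7a at -0.40 ± 0.11, twist1a at -0.43 ± 0.16, pax3a at -0.30 ± 0.13 and fam212aa at -0.19 ± 0.09.

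Among eye genes, the optic stalk and ventral retina list was lower by camera (median log2 change -0.11, 13 members; camera adjusted p = 0.0337; adjusted p = 0.456 with an estimated correlation), a call lost without normal embryo 6 (camera adjusted p = 0.304) or coloboma embryo 7 (0.109). No member passed over all genes, and vax2 and nr2f1b were lower when adjusted over the list alone. The ventral eye transcription factor vax2 measured 1.85 ± 0.456 CPM (SD, n = 4) and 0.943 ± 0.302 CPM (SD, n = 5). The nuclear receptor gene nr2f1b had a log2 value of -0.53 ± 0.15 (SE), foxg1a -0.47 ± 0.20 and vax1 -0.75 ± 0.38. Retinal progenitor genes had a median of -0.31 (20 members, camera adjusted p = 4.02e-05; adjusted p = 0.456 with an estimated correlation). None passed over all genes and 1, vsx1 (-0.47 ± 0.10), was lower when adjusted over the list alone. For the others by p, rx2 was at -0.65 ± 0.24, foxd1 at -0.44 ± 0.17 and mab21l1 at -0.27 ± 0.10. Coloboma embryo 3 lay apart in the eye lists. The mean log2 level of its 29 lens genes, mostly crystallins, was -3.40 relative to the normal embryos, against 0.14 to 0.77 in the other 4 coloboma embryos, and that of its retinal progenitor genes was -1.08. Without it the mean retinal progenitor level of the coloboma embryos went from -0.33 to -0.14, and the list still passed as lower (camera adjusted p = 0.00325), while the level over all 5 did not pass a two-sided exact permutation test (p = 0.214). The labels do not say whether this embryo was more severely affected or had lost tissue. The lens list itself did not pass (camera adjusted p = 0.837, direction down), although its median log2 change was 0.28, of the opposite sign. Without coloboma embryo 3 it passed as higher (camera adjusted p = 5.88e-15).

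Forebrain regional genes were lower as a list (median log2 change -0.35, 24 members; camera adjusted p = 1.83e-08; adjusted p = 0.413 with an estimated correlation), and coloboma embryo 3 again had the lowest level, -1.0 relative to the normal embryos. Without it the mean level of the coloboma embryos went from -0.43 to -0.29 and the list passed (camera adjusted p = 5.78e-07). The level over all 5 did not pass a two-sided exact permutation test (p = 0.0794). None passed over all genes and 4 were lower when adjusted over the list alone. The interneuron factor lhx6 measured 5.67 ± 0.511 CPM (SD, n = 4) and 2.53 ± 0.747 CPM (SD, n = 5), with an edgeR adjusted p of 0.0595. The genes dlx2a, otpb (-0.55 ± 0.14) and pou3f1 (-0.37 ± 0.11) were the other members. The list of hedgehog target genes was lower by camera (median -0.15, 16 members, camera adjusted p = 0.0232; adjusted p = 0.456 with an estimated correlation), a call lost without normal embryo 6 (camera adjusted p = 0.141) or coloboma embryo 5 or 7 (0.0565 and 0.124). None passed over all genes and 3 were lower when adjusted over the list alone. Those 3 were foxf2a (9.94 ± 2.51 CPM, SD, n = 4, and 5.26 ± 0.635 CPM, SD, n = 5; edgeR adjusted p = 0.0595) and foxl1 (-1.03 ± 0.24), forkhead genes of craniofacial mesenchyme, and olig2 (-0.34 ± 0.10), a motor neuron progenitor gene on the chromosome of zic2a. The next member, prdm1a, had a value of 0.27 ± 0.10. The receptor gene ptch1 (0.13 ± 0.15), a direct readout of the pathway that was chosen after its value was seen, did not pass by either adjustment. Of the 7 zic genes none passed over all genes and 3 were lower when adjusted over the list alone, among them zic6 (-0.43 ± 0.11) and zic5 (-0.30 ± 0.11, on the chromosome of zic2a). That list had a median of -0.13 (camera adjusted p = 0.0232; adjusted p = 0.552 with an estimated correlation), a call lost without normal embryo 6 (camera adjusted p = 0.176) or coloboma embryo 5 or 6 (0.0565 and 0.0723).

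Genes of differentiated skeletal muscle were higher as a list, with positive log2 values in 42 of 43 members and a median of 0.60 (camera adjusted p = 2.99e-22; adjusted p = 0.376 with an estimated correlation). One member, the fast myosin heavy chain myhz1.2, passed over all genes, rising from 2152 ± 365 CPM (SD, n = 4) to 3749 ± 405 CPM (SD, n = 5; edgeR adjusted p = 0.0490), and 29 were higher when adjusted over the list alone. The light chain mylpfb measured 0.85 ± 0.17, the troponin tnnt3a 0.61 ± 0.14 and the parvalbumin pvalb2 0.73 ± 0.17 (log2, SE). The 43 genes together took 5.58% ± 1.1 (SD, n = 4) of all counts in normal and 8.66% ± 1.67 (SD, n = 5) in coloboma embryos (two-sided exact permutation p = 0.0317). The call for myhz1.2 was lost in 18 of 29 alternative settings.

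**Figure D2:**
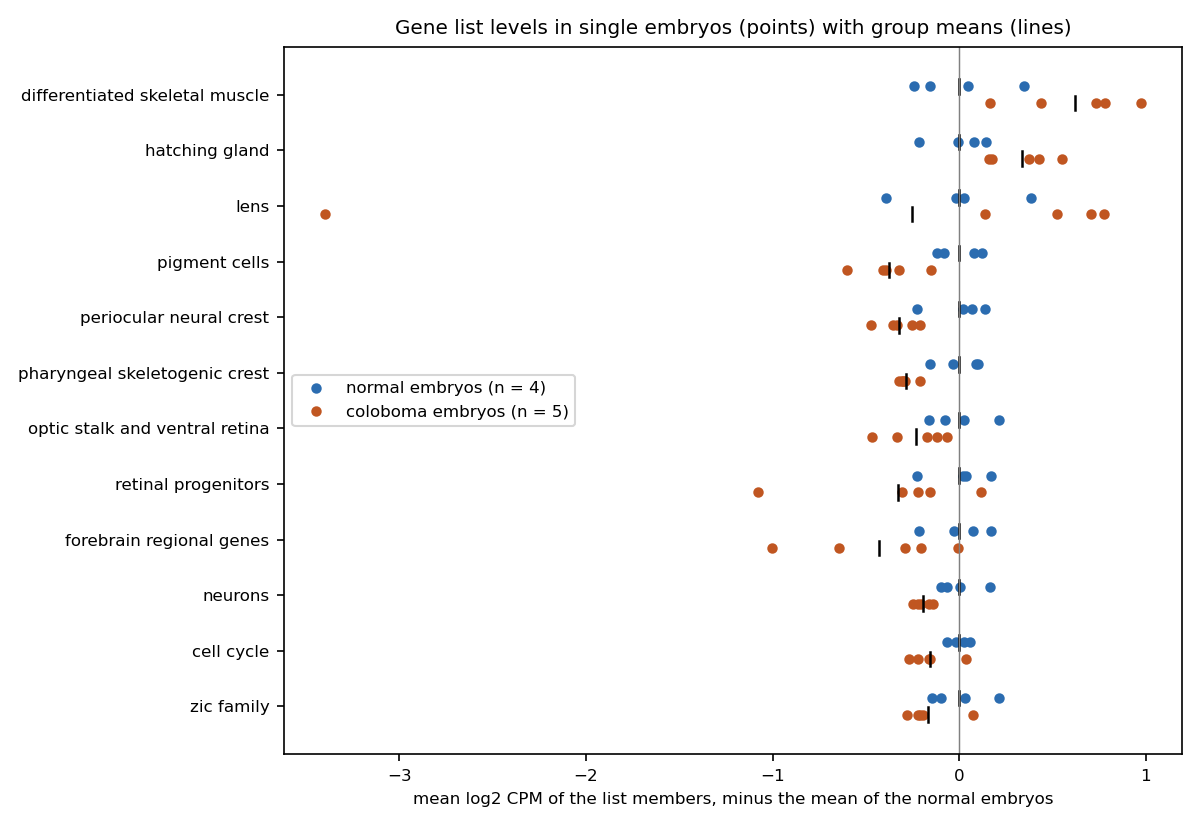
Mean log2 CPM of the members of 12 gene lists in each embryo, relative to the mean of the normal embryos (x axis, log2); points are the 4 normal and 5 coloboma embryos and short lines are group means. Coloboma embryo 3 lies at -3.40 for the lens list, and the coloboma embryos lie at 0.17 to 0.97 for skeletal muscle, where normal embryo 4 lies at 0.35, so that the groups overlap.

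Some of the larger changes lay outside these lists. The tight junction gene cldn11a fell from 6.79 ± 0.404 CPM (SD, n = 4) to 0.747 ± 0.212 CPM (SD, n = 5), a log2 change of -3.16 ± 0.19 (SE; edgeR adjusted p = 2.83e-05). Also lower away from the chromosome of zic2a were tmem130 (-1.04 ± 0.12, edgeR adjusted p = 0.00390) and the cation exchanger cax1 (-0.81 ± 0.10, adjusted p = 0.00639), and mtdhb was higher (2.22 ± 0.36, adjusted p = 0.0403), a call lost in 18 of 29 alternative settings. On the chromosome of zic2a the gene with the smallest p of all was si:dkey-100n23.4, chosen after its values were seen, which rose from 7.21 ± 0.911 CPM (SD, n = 4) to 51.6 ± 3.45 CPM (SD, n = 5; edgeR adjusted p = 4.15e-07). The axonemal dynein gene dnah7 rose from 3.56 ± 0.194 CPM (SD, n = 4) to 14.1 ± 2.69 CPM (SD, n = 5; edgeR adjusted p = 0.000225) and the potassium channel gene kcnh3 by 2.36 ± 0.23 on the log2 scale. Higher on that chromosome too were the co-chaperone gene dnajb2 (1.21 ± 0.11), arhgap20 (2.35 ± 0.27), asmtl (1.43 ± 0.17), the RNA helicase gene ddx18 (0.62 ± 0.09), the hemopexin gene hpx (1.32 ± 0.19) and srpx (0.61 ± 0.10). Lower there were ankrd44 (-1.02 ± 0.10), the pyridoxal kinase gene pdxka (-2.45 ± 0.27) and rnf17 (-2.10 ± 0.24).

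For one clone-named gene on the chromosome of zic2a no count was found in any coloboma embryo, while each normal embryo had 26 to 102 counts. Against a floor of 3 counts over the coloboma group its mean of 1.26 ± 0.507 CPM (SD, n = 4) was at least 90.3-fold higher in normal embryos, with counting error alone behind the floor. The clone-named gene AL935184.1, which could not be placed, had 601 counts in the normal and 1 count in the coloboma embryos, a ratio of 676 with an exact Poisson interval of 121 to 26743 (95%, counting error only). Both were chosen after their values were seen.

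The genes past the threshold were gathered on one chromosome. In the current reference annotation (assembly GRCz12tu, used for neighbourhood only), 15006 of the tested genes (70.5%) and 37 of the 44 genes past the threshold (84.1%) could be placed by symbol. The chromosome that carries zic2a held 19 of the 37 (51.4%, exact 95% interval 34.4 to 68.1) against 4.01% of the tested genes (one-sided Fisher exact p = 1.98e-17), 10 higher and 9 lower. The chromosome that carries zic2b held 1 (2.70%, interval 0.0684 to 14.2) against 4.50% of the tested genes (one-sided Fisher exact p = 0.819), and no other chromosome held more than 2. The other 18 placed genes comprised 5 higher and 13 lower. Along the 602 tested genes of the zic2a chromosome, those past the threshold lay from place 100 to place 465, with zic2a at place 375.

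**Figure D3:**
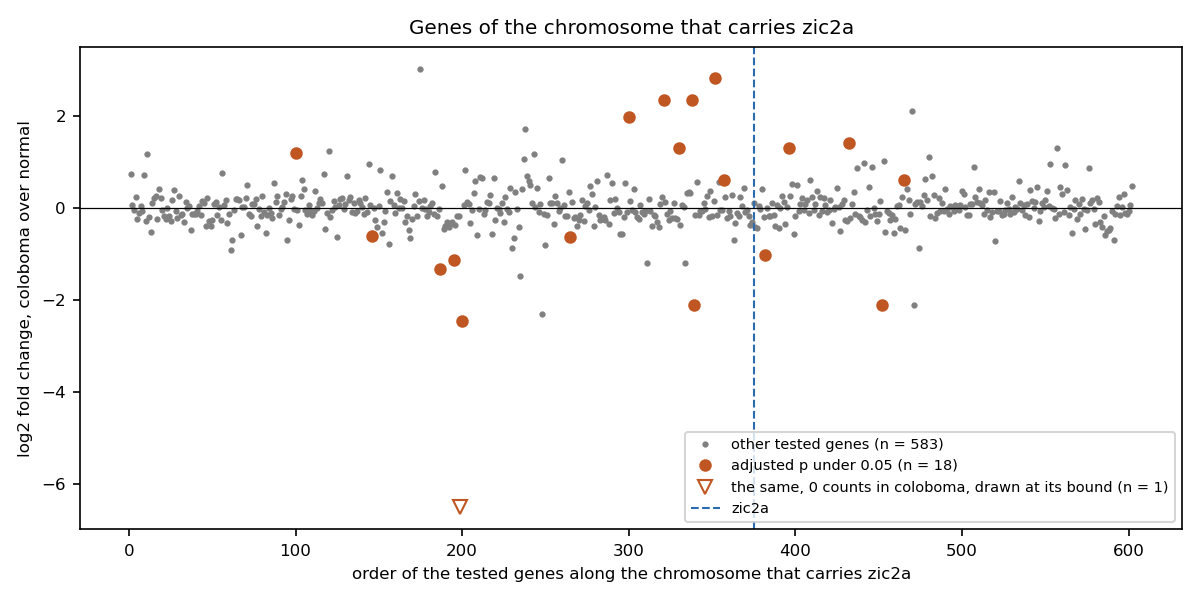
Log2 fold change of coloboma over normal embryos (y axis) for the 602 tested genes of the chromosome that carries zic2a, in their order along it (x axis, gene order, assembly GRCz12tu). Filled points are genes past the threshold, the open triangle is a gene with 0 counts in the coloboma embryos drawn at the bound that a floor of 3 counts gives, and the dashed line is zic2a; the 19 genes past the threshold lie between places 100 and 465.

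The number of genes past the threshold depended on single embryos: it was 21 without normal embryo 3 or without coloboma embryo 4, 25 without normal embryo 6, 27 without normal embryo 7 and 235 without coloboma embryo 5. By DESeq2 it was 578, and with the genes of the zic2a chromosome left out, an analysis added after the values were seen, 15 of 20691 genes passed, 1 higher and 14 lower. Only the adjustment was repeated there, on the same p values. Genes that could not be placed stayed in, so genes of that chromosome may remain among the 15.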

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

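The tests of a crossover in coloboma embryo 6, of embryo stage and of dilution by muscle RNA were chosen after the results were seen, as were the members of the pigment cell subsets; the other tests in this part were written down before their results were computed. A total of 164 groups of values were examined for an embryo far from the rest of its group, by Dixon's criterion at the 95% level. Of these groups 14 had such an embryo, where chance gives about 1 in 20 independent groups. Some of the genes were chosen after their values were seen, and the groups share the same embryos. The 14 can therefore not be held against that rate.

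Genes past the threshold were gathered on the chromosome that carries zic2a (one-sided Fisher exact p = 1.98e-17) and near zic2a on it, at a median distance of 75 genes against 150.5 over all 602 tested genes there (permutation p = 0.00783). A candidate explanation is a stretch of chromosome inherited with the disrupted zic2a allele, whose sequence variants change the levels or the read mapping of neighbouring genes, while an effect of zic2a itself on its neighbours stays open. The chromosome of zic2b showed no such gathering (one-sided Fisher exact p = 0.819; at most 14.2% of the placed genes by the 95% interval), and a local effect around zic2a cannot account for the 48.6% of placed genes that lie elsewhere (exact 95% interval 31.9 to 65.6). Coloboma embryo 6 was placed, for the 30 genes there with an adjusted p under 0.1, on a scale from the normal embryos (0) to the other coloboma embryos (1). Its median place was 1 over the first 21 genes in chromosome order and 0.60 over the last 9, which could mark a crossover. With 30 genes this cannot be told apart from chance, since the step did not pass (permutation p adjusted over 5 embryos = 0.0928) and coloboma embryos 5 and 7 had the same adjusted p.

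The fall of the 8 xanthophore and pteridine genes was weighed against a fall of all pigment cells alike. From the fixed pigment list, 4 xanthophore members, of which 3 passed over all genes, had a mean log2 change of -0.76. The 12 melanophore members, all negative, had -0.44. The difference between them, -0.32 per embryo, passed (two-sided exact permutation p = 0.00794, the smallest the design allows). These members were chosen after the pigment values were seen, and the 3 that passed make up most of the xanthophore side. List members with positive values, kita (0.03), paics (0.17) and slc3a2a (0.22), were in neither subset. The p therefore carries the choice of members and decides nothing by itself. A further fall of the xanthophore mean was set beforehand as evidence against fewer or delayed pigment cells of every kind, but the bound was ill chosen. RNA of whole embryos includes the pigmented retina, which also makes the melanin genes and may hide part of a fall in melanophores, and the iridophore genes that could decide were only 2. The linked stretch around zic2a cannot account for this group by a local effect, since 0 of its 7 placed genes lie on that chromosome (95% upper bound 41.0%). A smaller or later xanthophore population in embryos with coloboma stays open as an untested biological explanation.

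By camera's preset correlation the muscle list was higher and the neurons and neural progenitor lists were lower in the coloboma embryos, calls lost with an estimated correlation (adjusted p = 0.376, 0.376 and 0.413). Dilution by the larger muscle share would lower all other genes alike. Relative to the median of the 21214 genes outside the muscle and neurons lists, the neurons list was lower by a mean of -0.18 on the log2 scale (SD 0.116 in normal and 0.0420 in coloboma embryos, two-sided exact permutation p = 0.00794, not adjusted). The neurons level by itself had the same p, or 0.151 adjusted over the 38 lists. That list was picked after its fall was seen, and the median of the other genes moved by only -0.004, so the subtraction could hardly change the p. In shares of unscaled counts, the rise in muscle share would by itself lower all other genes by a log2 value of -0.048. The list levels are TMM-scaled, so that value is not on their scale. Dilution would lower the other genes as much, so the fall of the neurons list relative to them argues against dilution as the whole cause. A later stage of the coloboma embryos cannot be told apart. It should raise the melanin genes, and the 12 melanophore members, chosen after the values were seen, were lower (mean log2 change -0.44, two-sided exact permutation p = 0.0238). Fewer pigment cells would hide such a rise. A changed balance of head and trunk tissue stays open and was not tested.

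As many genes as the real 44 passed in 2 of 100 splits of the 9 embryos into 4 and 5, the real one included. Of the 126 possible splits only these 100 were run. So high a count was rare among them, but it does not by itself tie the calls to the phenotype, since another split gave more. The highest of the other splits gave 260 genes, and it set coloboma embryos 3, 4, 6 and 7 against the normal embryos together with coloboma embryo 5. This split differs from the real one only in the place of coloboma embryo 5. It keeps most of the phenotype contrast and is not a measure of chance alone. Leaving that embryo out gave 235 genes, with all 44 shared. Coloboma embryo 5 had the lowest total count and lay apart from the other 8 on the first principal component. Why its place changes the count so much was not tested. For the gene lists, 1 of 100 splits, the real one itself, gave as many as the real 20, with 19 as the highest of the others. The real number was thus the highest of the splits run, but by so little that chance is not firmly excluded. The other splits gave a median of 13 lists, so a single list past the threshold by camera's preset correlation is weak evidence.

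Coloboma embryo 3 lay far from its group in several measures, and the labels do not say whether it was more severely affected or had lost tissue. Its lens list level was -3.40 where the other coloboma embryos lay between 0.14 and 0.77, its zic family level was 0.0740 against -0.28 to -0.20, and its pharyngeal crest level was -0.21 against -0.32 to -0.29. It also had 1786 CPM of tnnt3a against 1181 to 1322 and 12.5 CPM of foxc1b against 8.13 to 9.17. Coloboma embryo 6 had 0.888 CPM of arhgap20 against 1.18 to 1.28 in the other coloboma embryos, 5.66 CPM of slc15a2 against 1.69 to 1.98 and 0.244 CPM of BX255936.1 against 4.14 to 4.61; the normal embryos had 0.223 ± 0.0648, 11.4 ± 1.11 and 0.101 ± 0.0509 CPM (SD, n = 4) of these genes, and slc15a2 and BX255936.1 were chosen after their values were seen. Coloboma embryo 5 had 12.8 CPM of slc2a15a against 9.95 to 10.7, coloboma embryo 7 had 4.06 CPM of gpr143 against 2.98 to 3.2, and coloboma embryo 4 held the single count of AL935184.1 in the group (0.0194 CPM). Among normal embryos, number 6 had 2.37 CPM of kcnh3 against 1.41 to 1.55, number 4 had 13.3 CPM of asmtl against 9.27 to 9.89, and number 7 had 7.50 CPM of pax7a against 6.30 to 6.45.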

How the results depend on the processing

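Leaving out coloboma embryos 3 and 5 together and leaving out the genes of the zic2a chromosome were added after the data were seen. The 44 genes past the threshold (17 higher, 27 lower) became 578 with DESeq2 (367 higher, 211 lower; all 44 shared) and 100 with sample quality weights (44 and 56; 41 shared). They were 19 at an adjusted p of 0.01 (8 and 11) or 86 at 0.1 (41 and 45). With a log2 change of at least 1 they were 27 (13 and 14). Leaving out one embryo at a time gave 21 to 235 genes, 8 to 165 higher and 11 to 70 lower. There were 21 without normal embryo 3 or coloboma embryo 4, 25 and 27 without normal embryos 6 and 7, 51 (29 higher) without normal embryo 4, and 235, with all 44 shared, without coloboma embryo 5. TPM input gave 11 higher genes under each of its 3 settings, of 34 or 35 in all. Without coloboma embryos 3 and 5 there were 60 genes, 32 higher. Without the genes placed on the zic2a chromosome there were 15 (1 and 14), all among the 25 of the 44 still tested. The embryo numbers were shared by both groups but did not pair the embryos. Deviations of same-numbered embryos correlated by -0.07, 0.07, 0.03 and -0.003, and of 4 numbers only number 4 matched its own best. With these numbers as a replicate block on 8 embryos 18 genes passed (10 and 8), 14 of them shared. Other scalings, filters, voom, robust edgeR and 1 surrogate variable gave 30 to 59 genes. With library sizes only the split was 12 higher and 33 lower, with the median of all genes shifted by -0.08. The cause of these differences was not tested, beyond the fewer genes or embryos that some settings hold. The 20 gene lists past the threshold (7 up, 13 down) became 0 with an estimated correlation, where 4 had an unadjusted p under 0.05, and 0 with fry's directional test, while fry's mixed test, for change in either direction, called 14. Under the other settings 15 to 22 passed. The lens list, not past the threshold with direction down, passed as higher with 1 surrogate variable (camera adjusted p = 0.0365), without coloboma embryo 3 (5.88e-15) and without coloboma embryos 3 and 5 (9.69e-10), with a range of 5.88e-15 to 0.987 when one embryo was left out. Coloboma embryo 3 holds its low lens values. Neither zic2a nor zic2b passed in any setting. Of the named genes, cldn11a, dnah7, dnajb2, kcnh3, asmtl, ankrd44, tmem130, si:dkey-100n23.4 and AL935184.1 stayed past the threshold, in the same direction, in every alternative that tested them. Calls were lost in 18 of 29 for mtdhb and myhz1.2, 16 of 29 for slc2a15b, 15 of 28 for srpx, 17 of 28 for BX255936.1, 11 of 28 for ddx18, 10 of 29 for PTS, 10 of 28 for slc15a2, 9 of 29 for sprb, 9 of 27 for hpx, 6 of 29 for xdh and 5 of 29 for aox3, and in 1 to 3 settings for gch2, pdxka, slc2a11b, slc2a15a, rnf17, cax1 and arhgap20. Conversely some genes that did not pass did so in part of the settings: foxf2a in 9 of 29, lhx6 in 6 of 29, otpb and mylpfb in 4 of 29, vsx1 in 3 of 29, alx1 in 3 of 28 and dlx4a and barx1 in 2 of 29. By DESeq2 alone zic6, alx4a, pax7a, gpr143, prrx1b, dlx2a, foxl1, vax2, nr2f1b, tnnt3a and pvalb2 did. Single-embryo totals were at least 20461180 counts, and at a log2 change of 0.5 only 26.0% of genes simulated at these totals were recovered. The embryo with the lowest total is coloboma embryo 5, without which 235 genes passed.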

Other observations

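The values in this part were read after the main results were seen, and no test was added for them. Beyond the lists described with the comparison, 11 further lists passed by camera's preset correlation and none did with an estimated correlation. Neuronal genes were lower (median log2 change -0.17, 36 members, camera adjusted p = 2.40e-07; adjusted p = 0.376 with an estimated correlation), with 0 members past the threshold over all genes and 3 lower when adjusted over the list alone: inab (-0.59), which encodes an intermediate filament of neurons, nhlh2 (-0.55), which lies on the chromosome of zic2a, and stmn1b (-0.46). Neural progenitor genes (median -0.18, camera adjusted p = 8.76e-07; adjusted p = 0.413 with an estimated correlation), cell cycle genes (-0.15, 2.50e-07; adjusted p = 0.456 with an estimated correlation), dorsal neural tube genes (-0.23, 0.00110; 0.456 likewise) and erythroid genes (-0.41, 8.40e-06; 0.552 likewise) were lower as lists too, with 4 members of the first and none of the other 3 lower when adjusted over the list alone.

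The endothelium list was higher (median log2 change 0.16, 24 members, camera adjusted p = 0.00122; adjusted p = 0.514 with an estimated correlation), and 3 members, stab2 (0.62), kdr (0.45) and clec14a (0.39), were higher when adjusted over the list alone. The list of fissure and basement membrane genes was higher as well (median 0.09, 23 members, camera adjusted p = 0.00261; adjusted p = 0.552 with an estimated correlation); its 2 members past the threshold when adjusted over the list alone were the neighbouring collagen IV genes col4a1 (0.62) and col4a2 (0.43), which lie on the chromosome of zic2a. Hatching gland genes (median 0.38, camera adjusted p = 0.00129; adjusted p = 0.376 with an estimated correlation), epidermis and ionocyte genes (0.14, 0.00129; 0.456 likewise), FGF targets (0.09, 0.0169; 0.552 likewise) and notochord and floor plate genes (0.16, 0.0232; 0.651 likewise) completed the lists that passed; agr2 (0.65) and foxi3b (0.46), genes of mucus-secreting and ionocyte cells, were higher in the epidermal list when adjusted over the list alone. No member of these lists passed over all genes by edgeR. Single embryos decided some of these calls: without coloboma embryo 3 the endothelium (camera adjusted p = 0.0532), FGF target (0.104) and notochord lists (0.183) did not pass, nor without normal embryo 7 the FGF target (0.124) and notochord lists (0.373), without coloboma embryo 4 the notochord list (0.0916) or without normal embryo 6 the epidermis list (0.0743).

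The lists that did not pass by camera were early and migrating crest, hedgehog ligands and co-receptors, dorsal retina and BMP, lens, retinoic acid pathway, Wnt targets, dermomyotome and sclerotome, segmentation and tailbud, heart muscle, myeloid cells, yolk syncytial layer, p53 pathway and cell death, stress and immediate early genes, circadian clock, left-right and cilia, pronephros, pituitary and hypothalamus, and mitochondrially encoded genes, with camera adjusted p from 0.165 to 0.913. With one embryo left out, 6 of these passed: yolk syncytial layer (higher, camera adjusted p = 0.0294) and stress genes (higher, 0.0310) without normal embryo 3, heart muscle (lower, 0.0329) without normal embryo 7, and early crest (lower, 0.0227), segmentation and tailbud (lower, 0.0382) and lens (higher, 5.88e-15) without coloboma embryo 3.

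Unadjusted p values below 0.05 were found for 2487 genes by edgeR, against 1065 that chance alone would give, and for 27.4% of the tested genes on the chromosome of zic2a against 11.8% of the placed genes elsewhere.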
